A study of Cucumis sativus with 6 samples.

How the data were processed

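RNA from cucumber (Cucumis sativus) fruits collected on the day of flower opening was sequenced in 6 libraries, 3 from each of the near-isogenic lines 32X and GFC. Near-isogenic lines share most of their genome after repeated crossing and differ mainly in retained donor segments. Per the labels' protocols, libraries were made with a strand-preserving Illumina kit and each line was sampled in 3 biological replicates. The labels do not say whether the replicates came from separate plants, so the p-values measure the spread between these samples. The genotype field holds the same entry for all 6 samples, so the lines were taken from the sample titles.

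The authors deposited 1 table of RPM values (reads per 1000000 counted reads) for 17073 gene models, with a column per library. Per the submitters' processing notes, TopHat and HTSeq were used. Their versions, the genome build, the annotation and any filter on low values are not given in the sources used here. Each column summed to 1000000 over the listed genes, so the RPM values are relative to the reads counted in those genes and not to all sequenced reads. Every listed gene had at least 1 RPM in at least 3 of the 6 libraries, and genes below that level were not analysed here. A gene on in all 3 libraries of 1 line and off in the other could still be listed.

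The RPM values of each library were whole multiples of the value of 1 read: 100% of the values came out whole within 0.001 reads in every library. In 32X replicate 3 the smallest value stood for 2 reads, and in the other 5 libraries for 1 read. The recovered totals ran from 15320600 to 18089654 reads per library, and 1 read was worth 0.0553 to 0.0653 RPM. A count of 3 reads, the limit that a count of 0 allows, corresponded to 0.166 to 0.196 RPM per library. Such limits and the 95% intervals of read ratios (exact Clopper-Pearson, on the share of a gene's reads in 1 line) cover counting error only, since reads made by PCR are not independent molecules.

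Differences between the lines were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with an intensity trend in the variance prior, no covariates and a two-sided test, and p-values were adjusted with the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are described as differing. The planned filter of at least 1 RPM in at least 3 libraries removed 0 genes. Fold changes are GFC minus 32X on the log2(RPM + 1) scale, which understates the change of low genes. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors) and DESeq2 1.42.0 (Wald test) as alternatives. Other alternatives were TMM, median-of-ratios and quantile scaling, pseudocounts of 0.1 and 5, a filter of at least 5 RPM in 3 libraries, library weights, the replicate number as a block, a fold limit, and leaving out each library in turn. The design, these alternatives and the rule for named genes were fixed before the data were examined. The groupings by expression class, by read count and by the chromosome code in the ID, with their tests, were added afterwards.

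In data simulated for the comparison of GFC with 32X on all 17073 genes, with the means, library sizes and dispersions of these libraries, limma recovered 49.3% of 67 genes changed by 1.5-fold, 89.6% of 67 genes changed by 2-fold and 98.5% of 66 genes changed by 4-fold. In that simulation 4.24% of limma's calls were false, against 5.36% for edgeR and 11.3% for DESeq2. Only those genes were changed in it, and noise was drawn independently for each library. In the data 20.6% of genes differed and replicates spread along a shared direction. These percentages therefore may not hold for the calls in the data.

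Gene symbols and descriptions were not used. The deposited table pairs its IDs with neither, and 0 rows of the RefSeq gene table of the Cucumber_9930_V3 assembly hold such an ID. The 23 gene lists prepared for the comparison (meristem, MADS-box, auxin, other hormones, growth, cell type markers, stress and metabolism) therefore matched 0 genes, and no list was tested. For the same reason the genes that the series title names were not analysed here. By the rule fixed for this case, the 2 genes with the largest rise and the 2 with the largest fall are named by ID. In the naming scheme of these cucumber gene models the character or pair of characters after Csa is the chromosome, with UN for unplaced sequence, and the serial number follows the order along it. Chromosomes are given by that code only, and no coordinates are reported. Genes next to each other in serial number among those listed are called neighbours.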

Results

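The transcriptome of the fruit on the day of flower opening was compared between the near-isogenic cucumber lines 32X and GFC, with 3 libraries of each line. The study concerns variation in carpel number, the number of fused units that form the fruit. The recovered depth was 16306424, 15320600 and 16960640 reads for 32X replicates 1 to 3 and 16131528, 17667364 and 18089654 for GFC replicates 1 to 3. The 10 most abundant genes took 3.09% to 3.64% of the reads of a library. Across genes, log2(RPM + 1) values correlated at 0.984 to 0.990 between 32X libraries, at 0.989 to 0.995 between GFC libraries and at 0.952 to 0.984 between lines. Replicates of a line differed by more than sampling noise, with a chi-square of at least 3.82 per degree of freedom, so no pair was treated as a repeat deposit of 1 library. This does not tell separate plants from separate preparations of the same RNA. The first principal component held 68.9% of the variance and separated the lines. Along it the 32X libraries ran from -40.9 to -13.1 and the GFC libraries from 21.2 to 32.9. By chi-square per degree of freedom, 32X replicate 1 was nearest to 32X replicate 3 (9.06). By this measure it was nearer to GFC replicates 1 and 3 (16.6 and 18.7) than to 32X replicate 2 (23.9). By correlation the order was the other way, with 0.9842 for 32X replicate 2 against 0.9835 and 0.9829 for GFC replicates 1 and 3.

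**Figure D1:**
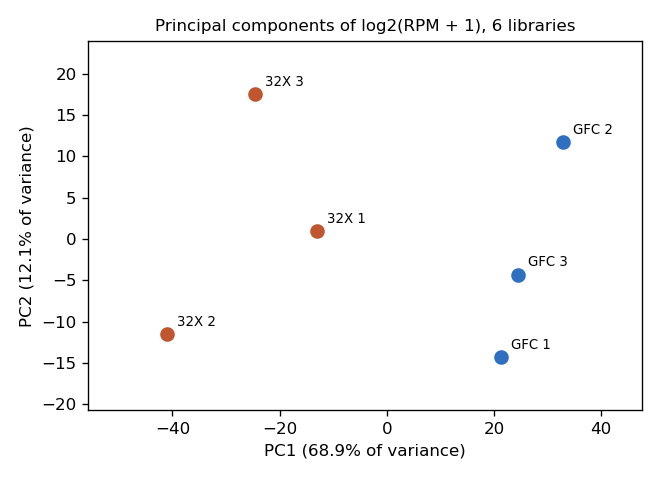
Scores of the 6 libraries on the first 2 principal components of log2(RPM + 1), with the share of variance on each axis. Each point is a library, labelled by line and replicate (orange 32X, blue GFC). All 32X libraries have negative and all GFC libraries positive scores on the first component, which holds 68.9% of the variance.

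The comparison of the lines asked which genes the fruit of GFC expresses at a different level from the fruit of 32X. Of the 17073 genes tested, 3517 (20.6%) differed, 1431 of them higher in GFC and 2086 lower (limma on log2(RPM + 1), Benjamini-Hochberg adjusted p under 0.05). Most of these differences were small: the median absolute log2 fold change was 0.56, and 87.3% of the differing genes changed by less than 2-fold. On the log2(RPM + 1) scale the larger differences lay mainly in the lower direction. On that scale 83 genes were at least 2-fold higher in GFC and 362 at least 2-fold lower. At least 4-fold changes numbered 12 higher and 25 lower. Among genes with a mean of at least 100 RPM, 38 changed by at least 2-fold, 7 of them higher and 31 lower in GFC. The genes lower in GFC took 16.1% ± 1.9 of the reads in 32X and 10.2% ± 0.36 in GFC (SD, n = 3). The genes higher in GFC took 9.21% ± 1.0 in 32X and 12.9% ± 0.45 in GFC (SD, n = 3). Both sets were chosen by direction in these libraries, so the direction of these differences in share was set by the choice. The libraries of the 2 lines did not overlap for 7410 genes (43.4%), where the average over all splits of the 6 libraries into 3 and 3 is 10%. Genes vary together, so a single split can lie far from that average. The shares for the other splits are not given here. edgeR's quasi-likelihood test on the recovered reads gave 3494 genes, 3316 of them also given by limma in the same direction. Leaving out 1 library changed the number of differing genes, to 4758, 2541 and 1942 without 32X replicates 1, 2 and 3. The number was 2216, 1633 and 1346 without GFC replicates 1, 2 and 3. A fit without 1 library has less power, so a fall by itself does not point to that library. Only without 32X replicate 1 did the number rise. With library weights 6684 genes differed. The fold counts depended on the scale, since the added 1 RPM shrinks the changes of low genes. With a pseudocount of 5 the 2-fold changes numbered 37 higher and 139 lower, and with a pseudocount of 0.1 they numbered 139 and 557. The 37 changes of at least 4-fold became 11 with a pseudocount of 5 and 106 with 0.1. Such changes numbered 124 in edgeR, 125 in DESeq2 and 57 without 32X replicate 1.

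**Figure D2:**
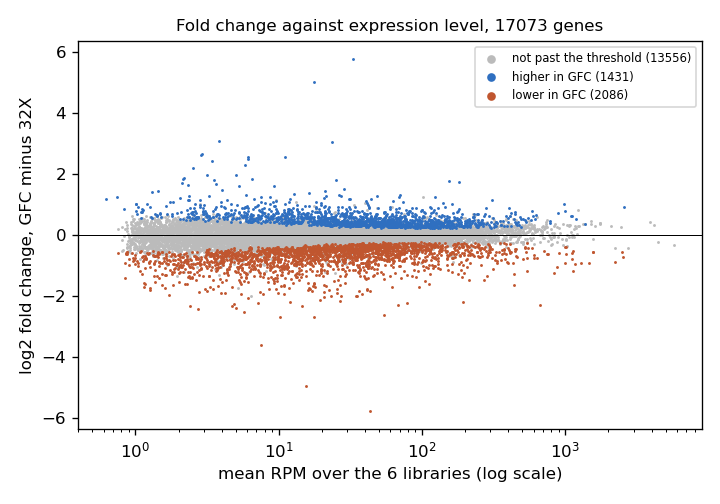
Log2 fold change (GFC minus 32X, on log2(RPM + 1) values) against mean RPM over the 6 libraries on a log axis, one point per gene. Blue points are the 1431 genes higher in GFC, orange points the 2086 genes lower in GFC at an adjusted p under 0.05, and grey points the other genes; large changes below the zero line outnumber those above it.

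With RPM as deposited, the direction of change varied with expression level. This gradient was kept under TMM and median-of-ratios scaling and in edgeR, and was absent after quantile normalization. The genes were divided into 4 classes of equal size by mean RPM over the 6 libraries. In the lowest class (0.625 to 9.02 RPM), 812 genes differed and 69.8% of them were lower in GFC. In the second class (9.02 to 25.8 RPM) 64.1% of 821 differing genes were lower, and in the third (25.8 to 60.4 RPM) 58.6% of 881. In the highest class (60.4 to 5690 RPM) 1003 genes differed, 526 higher and 477 lower, so that 47.6% were lower. The share of genes that differed moved less, from 19.0% in the lowest to 23.5% in the highest class. Changes of at least 2-fold made up 25.2% of the differing genes in the lowest class and 5.68% in the highest. These are shares of genes past the threshold. Standard errors were in general larger for low genes, so a change there had to be larger to pass. From the lowest to the highest class the lower share ran from 70.3% to 51.1% with TMM scaling. It ran from 68.9% to 48.5% with median-of-ratios scaling and from 71.6% to 53.3% in edgeR. After quantile normalization 52.9%, 52.3%, 54.3% and 54.6% of the differing genes were lower, from the lowest to the highest class. Quantile normalization gives every library the same distribution of values, so it can remove a level-dependent shift whatever its cause. The gradient also depended on single libraries: from the lowest to the highest class the lower share ran from 68.9% to 62.3% without 32X replicate 3, from 74.0% to 61.5% without GFC replicate 1, from 74.5% to 64.7% without GFC replicate 2 and from 75.5% to 68.3% without GFC replicate 3. It was wider without 32X replicate 1, from 70.5% to 41.3%, and ran from 69.1% to 52.4% without 32X replicate 2. In the highest class the majority was on the lower side with TMM scaling (51.1% lower), in edgeR's test on recovered reads (53.3%) and without 32X replicate 2 (52.4%) as well, and on the higher side without 32X replicate 1 (41.3% lower).

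**Figure D3:**
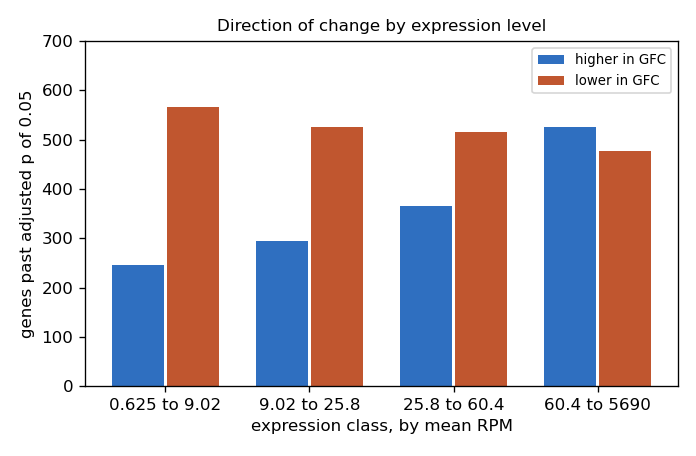
Number of genes past an adjusted p of 0.05 (vertical axis) in each of 4 equal classes of genes by mean RPM over the 6 libraries, with values as deposited (horizontal axis), with blue bars for genes higher and orange bars for genes lower in GFC. Lower genes outnumber higher genes in the first 3 classes, and higher genes (526) outnumber lower genes (477) in the last. This gradient is kept under TMM and median-of-ratios scaling and absent after quantile normalization. Its size depends on single libraries, wider without 32X replicate 1 and narrower without each of the others.

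By the chromosome code in their IDs, differing genes were spread evenly. Their share ran from 19.6% of 1680 genes on chromosome 7 to 21.3% of 2471 genes on chromosome 1. On chromosome 6 it was 20.9% of 2841 genes, and on chromosome 3, with the most genes, it was 20.3% of 3605. On every chromosome more genes were lower than higher in GFC, for example 325 against 202 on chromosome 1 and 228 against 177 on chromosome 4. The shares did not differ between the 7 chromosomes beyond chance for all differing genes (permutation p = 0.79, Benjamini-Hochberg adjusted over 3 tests 0.79) or for those changed by at least 2-fold (permutation p = 0.60, adjusted 0.79). Of the 37 genes changed by at least 4-fold, 12 were on chromosome 6 and 1 on chromosome 7, and this distribution did not pass the test either (permutation p = 0.17, adjusted 0.50). Among the 83 gene models on unplaced sequence 26.5% differed.

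A small group of genes was read almost entirely in 1 line. In 32X, 6 genes had at most 3 reads over the 3 libraries, and in GFC 7 genes did. Since every listed gene had at least 1 RPM in at least 3 libraries, each of these 13 genes was at that level or above in all 3 libraries of the other line, so a difference between the lines was set by how they were chosen. In the line where they were read, their mean level had a median of 5.77 RPM for the 6 genes low in 32X and 2.51 RPM for the 7 genes low in GFC. The highest such means were 35.1 and 30.9 RPM. With a limit of 10 reads in place of 3 the group held 18 genes. No read was counted for 2 genes in 32X and for 3 genes in GFC. Against a floor of 3 reads over the 3 libraries of the other line, these 5 genes were at least 20.3-fold to at least 125-fold higher in the line where they were read.

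The genes with the largest changes in each direction on the log2(RPM + 1) scale are on chromosomes 6 and 5 by their IDs. Which gene of a direction changed more depends on the scale: on log2(RPM + 1) Csa6G521020 exceeded Csa6G176420 and Csa5G523090 exceeded Csa5G115670, and with a pseudocount of 0.1, in edgeR and by read rate the order was the opposite in both directions. With a pseudocount of 0.1 the rising genes were nearly level, at log2 fold changes of 7.73 for Csa6G521020 and 7.75 for Csa6G176420. Csa6G521020 rose from 0.231 ± 0.143 RPM in 32X to 66.1 ± 1.38 RPM in GFC (SD, n = 3), with 11 reads against 3427 and a log2 fold change of 5.77 ± 0.13 (SE, limma adjusted p = 2.82e-08). The read rate was 292 times higher in GFC, with a 95% interval of 163 to 585. Csa6G176420 rose from 0.064 ± 0.0653 RPM in 32X to 35.1 ± 13.9 RPM in GFC, with 3 reads against 1842. Its log2 fold change was 5.01 ± 0.25 (limma adjusted p = 9.67e-06), and its read rate was 575 times higher in GFC (interval 196 to 2790). Csa5G523090 fell from 85.6 ± 15.7 RPM in 32X to 0.609 ± 0.409 RPM in GFC. It had 4140 reads in 32X and 32 in GFC, a log2 fold change of -5.76 ± 0.19 (limma adjusted p = 5.34e-07) and a read rate 138 times higher in 32X (interval 97.7 to 202). Csa5G115670 fell from 30.9 ± 4.17 RPM to 0.0184 ± 0.0319 RPM, with 1496 reads in 32X and a single read in GFC. Its log2 fold change was -4.96 ± 0.14 (limma adjusted p = 2.09e-07), and the ratio of read rates was 1600 with an interval of 286 to 63100. What these 4 genes encode is not given in the sources used here.

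**Figure D4:**
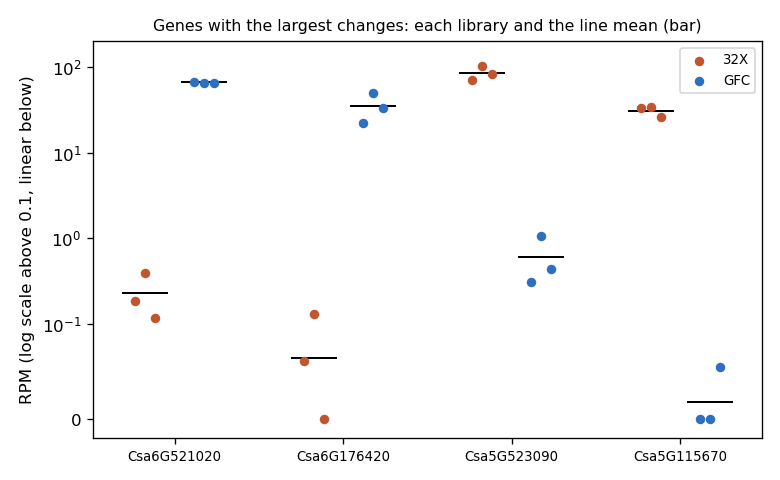
RPM of the 4 genes with the largest changes in each of the 6 libraries (points, orange 32X and blue GFC) with the mean of the 3 libraries of a line as a bar. The vertical axis is logarithmic above 0.1 RPM and linear below. In each gene the 3 libraries of 1 line lie above 20 RPM and those of the other line near or below 1 RPM.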

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

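The direction of every one of the 3517 differing genes was kept under TMM, median-of-ratios and quantile scaling, in edgeR's and DESeq2's tests on recovered reads, and without each library in turn. These genes were chosen for a difference in the same libraries, so the kept direction was largely set by the choice. Under the 3 scalings and both count tests 3132 to 3441 of them passed the threshold. The count of differing genes stayed within 1.5 times of 3517 under those scalings and count tests, under both other pseudocounts and with a filter of at least 5 RPM in 3 libraries, which left 14400 genes. Removing the filter changed nothing, since it removed no gene. Leaving out 1 library gave 1346 to 4758 differing genes, 384 to 2078 higher and 962 to 2680 lower in GFC, with the highest values without 32X replicate 1 and the lowest without GFC replicate 3. Library weights gave 6684 genes, 3236 higher and 3448 lower, and the cause was not tested. A log2 fold limit of 1 left 445 genes, 83 higher and 362 lower, by its construction. With the replicate number as a block, 2066 genes differed, 683 higher and 1383 lower, and the cause was not tested. The block leaves fewer degrees of freedom for the spread, so this fit has less power. A fall in the count by itself therefore does not point to a shared effect of the numbers. The labels give the numbers no shared batch or day. Deviations from the line means of the same-numbered libraries correlated across genes at -0.04, -0.27 and -0.09. No library of 32X correlated best with the GFC library of its own number. With 3 libraries per line, these values cannot exclude a small effect shared by same-numbered libraries. Changes of at least 2-fold numbered 83 higher and 362 lower with a pseudocount of 1, 139 and 557 with 0.1, 37 and 139 with 5, 140 and 579 in edgeR and 143 and 574 in DESeq2. All 68 values of the 4 named genes under the alternatives, DESeq2 added, kept their direction and stayed past the threshold, with a largest adjusted p of 0.000329. These genes were chosen for the largest changes in the same data, so this outcome was largely set by the choice. At this depth a gene with no read in a library is bounded only at 0.166 to 0.196 RPM. The tests planned for gene lists, with their alternatives of an estimated correlation and of fry, were not run because no list matched a gene. The 2-fold counts and the counts of low-read genes under alternatives were chosen after seeing the data.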

Other observations

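The count of splits, the thinning of reads, the placement of large changes by ID and the test without each 32X library were chosen after the result was seen. The tests on held-out replicates, on abundant genes, on read ratios of neighbours and on scaling were set down before their results were seen.

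Of the 13 genes read almost entirely in 1 line, 6 were on chromosome 6, which holds 16.6% of the listed genes, 3 of them low in 32X and 3 low in GFC. Over all 7 chromosomes their distribution gave a permutation p of 0.028, and 0.11 adjusted over the 4 sets of genes tested this way, so it did not pass. They included 2 pairs of neighbours (one-sided permutation p = 4e-05, not adjusted). The pair of Csa6G176420 and Csa6G176430 is also among the neighbours changed by at least 4-fold described below, so the results for neighbours are not independent. Over all listed genes, the log2 fold changes of neighbours correlated at 0.12, those of genes 2 places apart at 0.05 and those 5 places apart at 0.02, where the largest absolute value in 1000 permutations of the order was 0.025. Without the genes with large changes the values were 0.08, 0.04 and 0. These correlations are across genes, which are not independent replicates. The rows of the deposited table followed the strength of the line difference: the row number and the p-value correlated at a Spearman rho of 0.990 for limma and 0.991 for edgeR.

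The number of differing genes was 3517 for the split by line, and the highest number for any other split of the 6 libraries into 3 and 3 was 0. Only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

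Replicates of a line differed from each other along the same direction in which the lines differ. For each pair of replicates of a line, the difference between them was correlated across genes with the difference of the third, held-out replicate from the other line, which shares no library with the first difference. The median absolute correlation over the 6 pairs was 0.24, and 5 of the 6 lay between 0.22 and 0.46, the highest for 32X replicates 1 and 2. This argues against independent noise in each library, and the median of 0.22 without the top 10% of genes by mean RPM argues against a few abundant genes. Depth cannot be told apart from other causes: the totals differ too little for thinning to 15320600 reads, which removed at most 15.3% of a library and left the median at 0.23, to decide. Within each line the position of the 3 libraries along this direction and their reads had a rank correlation of 0.50: the library with the fewest reads lay nearest the 32X side in both lines, and the one with the most reads was furthest toward GFC in neither. A biological difference between the fruits sampled, such as their stage, was not tested and stays open.

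Some of the genes with the largest changes were neighbours. Among the 37 genes changed by at least 4-fold there were 3 pairs of neighbours, each changing in the same direction, 2 of them 10 serial numbers apart and 1 of them 5000 apart, where permuted placement gave 0.078 pairs on average (one-sided permutation p = 5e-05), which argues against chance placement. Both named genes that rose, Csa6G521020 and Csa6G176420, belong to such a pair. The count was 9 pairs with a pseudocount of 0.1 and in edgeR (among 106 and 124 genes past the fold limit), 10 in DESeq2 (among 125), 5 without 32X replicate 3 (among 42) and 0 with a pseudocount of 5 (among 11). Confinement of the large changes to 1 chromosome is argued against, since no more than 32.4% of the 37 genes lay on any 1 chromosome. The highest share was on chromosome 6, which holds 16.6% of the listed genes and both pairs that were 10 serial numbers apart. This spread cannot tell whether a difference on 1 chromosome changed genes on others. Smaller donor segments kept in 1 line, deletions, and sequence differences that keep reads of 1 line from mapping may each place large changes near each other and were not tested. Reads shared between similar gene models cannot be told apart from separate expression, because the log2 ratio of the reads of a pair varied between libraries by a median of 0.50 over only 3 pairs, between the limits set for either reading.

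More genes were lower than higher in GFC. Under the 3 other scalings the share of lower genes among those differing was at least 53.6%, the value after quantile normalization, so these scalings did not remove the majority, although with library weights it was 51.6% and quantile normalization removed its gradient with expression level. Leaving out each 32X library left at least 56.3% lower, which argues against 1 library of 32X as the sole source. Among changes of at least 2-fold the share was 81.3% as deposited and 74.0% after quantile normalization. The cause stays open, and a true difference between the lines is among the untested explanations.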
